A study of Rattus norvegicus with 6 samples.

How the data were processed

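Gene expression was measured by strand-specific RNA sequencing of polyadenylated RNA from 6 samples of rat vascular smooth muscle cells, 3 with a CRISPR-dCas9 guide that activates MIAT and 3 with a control guide. Per the labels' protocols, libraries were made from RNA of acceptable integrity by oligo(dT) selection, fragmentation and a dUTP second strand, and read as paired ends on a DNBSEQ-T7 instrument. The submitters' processing notes name HISAT2, DESeq2 and the genome build Rnor_6.0, without versions or roles. The read counter, the annotation release and whether counting used the strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may have been divided in an unknown way. Selection on poly(A) tails means that transcripts without one are under-represented.

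The authors deposited 2 tables of the same 32883 Ensembl gene identifiers. The first holds raw counts, per the file headers 1 column per sample, and no sample was pooled. The second is named by the authors for FPKM, but its deposited values are CPM, counts scaled to a library total of 1000000: for all but 5 genes each value equalled the count divided by the sample's total and put on the CPM scale, to a relative tolerance of 0.001, with no gene length. The 5 exceptions had at most 25 counts in any sample and differed from their CPM by constant factors between 0.715 and 10.99. Column sums were therefore 1000011 to 1000017. Multiplying CPM by the library total gave whole reads, to within 0.01, for 99.985% of values above 0, and the main test on those reads called 0 genes. Values in that table are not comparable between genes of different length. The analyses planned for FPKM were run on these CPM values. No per-sample column was left unmapped.

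Samples were assigned to groups, numbers, tests, gene lists and alternatives before the data were examined. The main test was edgeR 4.0.16 under R 4.3.3, with its quasi-likelihood F test on the counts, TMM scaling, the default filter (a minimum count of 10 and a minimum total of 15, which kept 12044 genes), the 2 groups as the only term and Benjamini-Hochberg adjustment at 0.05. SEs of edgeR fold changes were taken as the fold change divided by the square root of F. Group means and SDs are of CPM after TMM scaling. Alternatives were RLE size factors or library totals in place of TMM, no filter, a filter of 10 CPM in 3 samples, DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1, on log2 of CPM plus a pseudocount of 1 or 0.1, with a mean CPM of at least 0.5 or no filter), the replicate number as a block, and each of the 6 samples left out in turn. Alternatives added after seeing the data are named as such with the other checks.

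The rule for naming genes asked for gene symbols. The reference table used here holds 47357 rat genes of another assembly, GRCr8, and pairs 0 of the identifiers with a name, so no symbol, position or exon structure is given. Miat, Dhx9 and the 21 gene lists fixed beforehand (smooth muscle, cell cycle, nucleolus, stress and interferon programmes, other cell types of the vessel and genes flanking MIAT) were not analysed here. Since no gene passed the threshold, the rule's fallback applied, the genes with the smallest p in each direction. It was cut here to 2 in each direction, fewer than the rule had set. Contamination by other cell types was not assessed.

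The labels give both groups the numbers 1 to 3. The block takes these numbers to pair the samples. Across genes, the deviations of same-numbered samples from their group means correlated above 0.1 for every number (r = 0.730, 0.126 and 0.335 for numbers 1, 2 and 3). Other pairs were as close or closer: r was 0.630 for sg-MIAT 2 with sg-U6 3 and 0.337 for sg-MIAT 3 with sg-U6 2. Crossing numbers 2 and 3 gave a higher mean r (0.566) than matching by number (0.397). The labels state no pairing and the data do not single this one out. The edgeR and DESeq2 counts of calls with the block are therefore only given beside the main ones.

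No 2 libraries were duplicates: the chi-square per degree of freedom between libraries over genes with enough counts was at least 20.8, where sampling noise alone gives about 1. The fits were tested on simulated data drawn from the samples' library sizes and from means and dispersions fitted by edgeR. In these data 200 genes were changed 2-, 4-, 8- or 16-fold. Genes were drawn independently of each other, in a single draw per design. Without the block, the simulated samples shared no structure across the guides, unlike the real ones. Total counts per sample set the counting precision, and exact Poisson 95% intervals are given for low counts. Reads carry no molecular identifiers, so such intervals cover counting error only.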

Results

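Polyadenylated RNA was sequenced from rat vascular smooth muscle cells, the contractile cells of the vessel wall, in 2 groups of 3 samples. In the first group, sg-MIAT, a CRISPR-dCas9 system with a guide against the long non-coding RNA MIAT was used to raise its expression from the genome. The second group, sg-U6, received the same system with a negative control guide. Nuclease-dead Cas9 binds its target without cutting it, and in activation systems it carries or recruits factors that drive transcription. Total counts assigned to genes ran from 13128977 in sg-MIAT 1 to 18257865 in sg-MIAT 2, with means of 15882030 ± 2585168 (SD, n = 3) in sg-MIAT and 14536201 ± 839305 (SD, n = 3) in sg-U6. Of the 32883 Ensembl gene identifiers in the table, 18366 had at least 1 count in any sample. The labels number the samples of each group 1 to 3 but do not say whether they came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. The sources used here pair none of the identifiers with a gene name, so genes are given by identifier, and the targeted transcript Miat and the helicase gene Dhx9 were not analysed here. The labels were therefore not checked against the level of the targeted gene.

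The comparison asked which transcripts differ between cells given the MIAT guide and control cells. The genes with the smallest p in each direction were 2 that were higher and 2 that were lower in sg-MIAT, by 3.84- to 5.50-fold. ENSRNOG00000010635 reached 207.5 ± 60.6 CPM (counts scaled to a library total of 1000000) in sg-MIAT against 41.1 ± 2.64 in sg-U6 (mean ± SD, n = 3 each), a fitted 5.05-fold difference. ENSRNOG00000016412 was present at 11.4 ± 2.19 CPM in sg-MIAT and 2.07 ± 0.644 in sg-U6 (SD, n = 3), a 5.50-fold difference. In the opposite direction, ENSRNOG00000005809 averaged 12.5 ± 1.70 CPM in sg-U6 and 2.46 ± 0.403 in sg-MIAT (SD, n = 3), 5.07-fold lower in sg-MIAT. ENSRNOG00000057880 averaged 285.5 ± 67.4 CPM in sg-U6 and 74.2 ± 16.5 in sg-MIAT (SD, n = 3), 3.84-fold lower in sg-MIAT. For each of these 4 genes the lowest sample of the higher group lay above the highest sample of the other, so all 3 same-numbered pairs necessarily differed in the same direction. The genes were picked for the smallest p in these same samples, so this separation is no independent support.

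ENSRNOG00000010635 had 3213, 3487 and 2639 counts in sg-MIAT 1, 2 and 3 and 616, 593 and 623 in sg-U6 1, 2 and 3. ENSRNOG00000057880 had 647, 1490 and 1444 counts in the sg-MIAT samples and 5050, 3149 and 4563 in the sg-U6 samples. ENSRNOG00000005809 had 30, 37 and 47 counts in sg-MIAT against 173, 204 and 179 in sg-U6. The lowest count among the 4 genes was 24, for ENSRNOG00000016412 in sg-U6 2, whose exact Poisson 95% interval of 15.4 to 35.7 counts lay below the interval of 120.5 to 168.5 around the lowest sg-MIAT count of 143. These intervals cover counting error only.

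**Figure D1:**
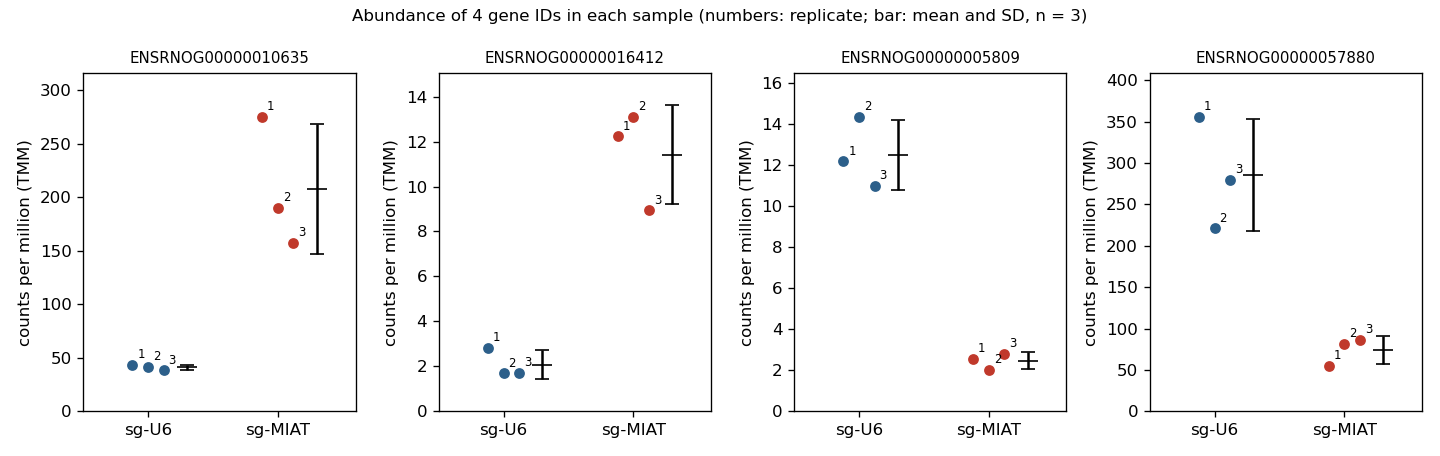
CPM after TMM scaling (y axis, linear, from 0) in each of the 3 sg-U6 (blue) and 3 sg-MIAT (red) samples for 4 gene identifiers; points are samples marked with their replicate number, and bars are the mean and SD. The 3 sg-MIAT samples of ENSRNOG00000010635 lie between 157.4 and 274.9, all above the sg-U6 samples at 38.2 to 43.4, and those of ENSRNOG00000057880 lie between 55.4 and 86.1, all below the sg-U6 samples.

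None of these 4 differences passed the test across all genes. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change (sg-MIAT over sg-U6) of ENSRNOG00000010635 was 2.34 ± 0.24 (SE) with an adjusted p of 0.405. For ENSRNOG00000016412 it was 2.46 ± 0.33 (SE) with an adjusted edgeR p of 0.628. The edgeR log2 fold change was -2.34 ± 0.26 (SE) for ENSRNOG00000005809, with an adjusted edgeR p of 0.405. It was -1.94 ± 0.26 (SE) for ENSRNOG00000057880, with an adjusted edgeR p of 0.628. DESeq2, which the submitters' processing notes name, placed all 4 past the threshold, with adjusted p-values of 2.45e-12, 8.49e-08, 2.05e-11 and 2.56e-07 in the same order. It also called each of the 4 in all 6 fits that left out 1 sample, with adjusted p-values of at most 0.00521. The 4 genes were picked on these same samples, most of which each such fit reuses, so the repeated calls are no independent support. In edgeR, none of the 4 was called with any sample left out. With 3 samples against 3, an exact two-sided permutation test of a single gene cannot go below p = 0.1.

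Across the transcriptome, edgeR called 0 of 12044 tested genes at an adjusted p under 0.05, and the smallest adjusted p was 0.405. At an unadjusted p under 0.05 it found 477 genes, 238 higher and 239 lower in sg-MIAT, where 602 would be expected by chance if the samples were independent. That unadjusted count was 184 without sg-MIAT 1, 242 without sg-MIAT 2 and 1470 without sg-U6 1. With the replicate number as a block, edgeR again called 0 genes, the smallest adjusted p was 0.243, and 918 genes had an unadjusted p under 0.05. limma-voom also called 0 genes, with 419 at an unadjusted p under 0.05, or 1060 with the block.

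DESeq2 called 60 genes at an adjusted p under 0.05, 37 higher and 23 lower in sg-MIAT, and 730 at an unadjusted p under 0.05. With the replicate number as a block it called 130 genes, 71 higher and 59 lower, of which 48 were shared with the 60. Overlap was assessed for the 58 of the 60 genes that passed the edgeR filter. Of these, 57 had no overlap between groups in CPM, which their selection on the same samples favours. The number of DESeq2 calls was 13 without sg-MIAT 1, 16 without sg-MIAT 2, 171 without sg-MIAT 3, 218 without sg-U6 1, 13 without sg-U6 2 and 39 without sg-U6 3. In the full fit and in all 6 of those fits, 9 genes were called, 4 higher and 5 lower in sg-MIAT, among them the 4 genes given by identifier. On data simulated for this comparison with 12044 genes, of which 200 were changed, 50 of 195 DESeq2 calls were false, against 6 of 120 for edgeR over the 11862 genes it tested. With the block in the simulation, 33 of 201 DESeq2 calls were false, against 19 of 179 for edgeR over the 11894 genes it tested. The simulations lack the correlation between genes of the real samples, so these rates may not hold in the real data. Their means and dispersions were fitted by edgeR, which may favour edgeR over DESeq2.

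Most genes differed little between the groups relative to the spread of replicates. The median absolute log2 fold change over the 12044 tested genes was 0.19, and the median SE was 0.30. A difference of at least 1 on the log2 scale was fitted for 196 genes higher and 612 genes lower in sg-MIAT, none of which passed the edgeR test. The size of this imbalance depended on the fit: limma-voom gave 220 higher and 386 lower, edgeR with the replicate block 211 and 458, edgeR with library totals alone 165 and 699, and edgeR with a filter of 10 CPM in 3 samples 58 and 112. On log2 of the deposited CPM plus 1, limma-trend gave 103 higher and 208 lower, and DESeq2, over more genes of low count, gave 1019 and 2016. Without sg-U6 3 the excess of lower genes was smaller, with 303 higher and 356 lower by this margin. Without sg-MIAT 2, sg-MIAT 3 or sg-U6 1 the higher genes numbered 211, 365 and 522 and the lower genes 970, 961 and 1099. Groups did not overlap for 1089 genes (9.04%), 560 higher and 529 lower in sg-MIAT, where chance gives 10% for 3 samples against 3 that are exchangeable. The samples share structure across the guides, so the 10% is only a rough reference, and 9.04% does not show an absence of guide differences. In the simulation without the block, edgeR recovered 0% of genes changed 2-fold, 63.3% of those changed 4-fold and 78% of those changed 8-fold. DESeq2 recovered 26%, 76% and 92%, with the larger share of false calls given above. Differences of 2-fold were thus not detectable by edgeR in that simulation, which leaves out the shared structure of the real samples. In a simulation of the fit with the block, over 11894 tested genes, 42% of genes changed 2-fold and 87.2% of those changed 4-fold were recovered. Each simulation changed many genes at once, some of them by 8-fold or more. Under Benjamini-Hochberg adjustment, many strong changes loosen the cutoff on the unadjusted p for all genes. The recovery rates of all these simulated fits may therefore not carry over to a small set of changed genes, which was not simulated.

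The main axis of variation did not separate the guides. Over log2 CPM across genes, sg-MIAT 1 was closest to sg-U6 1 (r = 0.964), and sg-MIAT 3 and sg-U6 2 were each other's closest sample (r = 0.983). The closest sample carried the same guide for sg-MIAT 2, which was nearest to sg-MIAT 3 (r = 0.972), and for sg-U6 3, which was nearest to sg-U6 2 (r = 0.970). The lowest correlation, 0.866, was between 2 samples of the control guide, sg-U6 1 and sg-U6 3. Genes are not independent replicates, so no test was attached to these correlations. The first principal component held 65.2% of the variance and placed sg-MIAT 1 at -59.9 and sg-U6 1 at -69.7, with the other 4 samples between 11.1 and 73.9. The second component held 17.4% of the variance, and the 3 sg-MIAT samples scored lower on it, from -36.3 to 5.28, than the 3 sg-U6 samples, from 9.93 to 37.6. Of the total variance over the 12044 genes, the guide took 16.3% with 1 degree of freedom and the replicate number 61.6% with 2, where independent samples would give 20% and 40%. In the edgeR fit with both terms, the replicate number reached an unadjusted p under 0.05 in 2988 genes and an adjusted p under 0.05 in 0 genes, with a smallest adjusted p of 0.106.

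**Figure D2:**
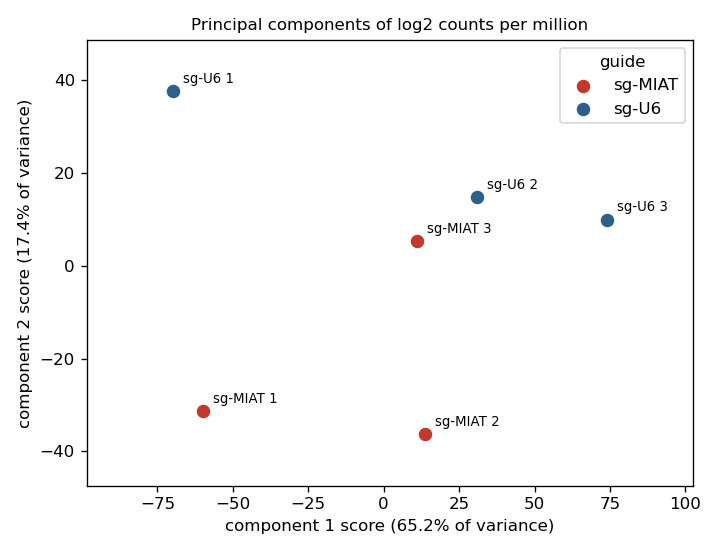
Scores of the 6 samples on the first (x axis) and second (y axis) principal components of log2 CPM, in arbitrary units, coloured by guide and marked with group and replicate number. sg-MIAT 1 and sg-U6 1 both lie on the left, at -59.9 and -69.7, apart from the other 4 samples, and the second component runs from sg-MIAT 2 at -36.3 to sg-U6 1 at 37.6.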

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

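Tests chosen after seeing the data were the DESeq2 and limma-voom fits with the replicate block, edgeR with bias-adjusted deviances, edgeR on the reads recovered from CPM, the fits without both samples numbered 1 and the DESeq2 fits that left out samples. Of the 23 alternatives to the main count of 0 genes, 21 also called 0, of which 2 were stricter thresholds on the same fit that could give no other count, and DESeq2 called 60 genes without and 130 with the replicate block. The edgeR fit with the replicate block called 0. The block changed no call of the 4 named genes in edgeR, DESeq2 or limma-voom, although it moved their adjusted p-values in each. Leaving out 1 sample gave 0 edgeR calls each time, with 184 to 1470 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0536, without sg-MIAT 3. DESeq2 called between 13 and 218 genes when 1 sample was left out, 13 without sg-MIAT 1 or sg-U6 2 and 218 without sg-U6 1, and 120 genes without both samples numbered 1, of which 28 were among the original 60. For the 4 named genes, the smaller DESeq2 p-values went with nearly equal fold changes and larger SEs. SEs were 0.285, 0.368, 0.297 and 0.298 in DESeq2 against 0.239, 0.331, 0.261 and 0.260 in edgeR, in the order ENSRNOG00000010635, ENSRNOG00000016412, ENSRNOG00000005809, ENSRNOG00000057880. Larger effects or a smaller SE therefore do not account for the gap in these genes. Their unadjusted edgeR p-values, 4.06e-05, 0.000209, 6.73e-05 and 0.000204 in that order, were already larger than the adjusted DESeq2 ones. The gap thus arises before adjustment, in how each tool turns a fold change and SE into a p-value. Which part of that step differs was not tested. All 83 values of the 4 named genes under alternatives kept their direction, and 8 passed the threshold, all from DESeq2. The shared direction was all but fixed in advance, since the groups did not overlap for these genes, so it is no sign of robustness. Adjusted p-values of ENSRNOG00000010635 ran from 4.49e-21 in DESeq2 with the block to 0.9998 in edgeR without sg-U6 2. The Miat and gene list alternatives were not run, since no identifier was paired with a name. The common coefficient of variation between samples was 0.388, or 0.264 with the block, and the count of calls was not recomputed at another depth.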

Other observations

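Of the tests below, thinning the libraries was set before its result was seen, and the others were chosen after. Of the 10 splits of the 6 samples into groups of 3, all 10 gave at least as many edgeR calls as the real one (0 genes, against a highest of 4 in another split), which a real count of 0 fixes in advance and which therefore says nothing about chance. For DESeq2, 3 gave at least as many calls (60 genes, against a highest of 630). With 10 splits no share under 0.05 can be reached. The split with 630 set sg-MIAT 1, sg-MIAT 2 and sg-U6 1 against the rest, several times the real count, which points to a structure of the samples. Of the 4 splits that keep both samples numbered 1 together, it is one, and the others gave 198, 5 and 4 calls, so that pair alone does not account for the high counts. Among the 4 splits that part all 3 same-numbered pairs, fitted with the block, the real split gave the most DESeq2 calls (130, against 52, 31 and 2) and the most edgeR genes at an unadjusted p under 0.05 (918, against 754, 312 and 139).

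The most prominent pattern is that sg-MIAT 1 and sg-U6 1 lie apart from the other 4 samples on the first principal component. Their deviations from their group means correlated at 0.730 across genes. Deviations within a group sum to 0, so this value also reflects sg-U6 3, at 73.9 on the opposite end of that component. The deviations of sg-U6 3 correlated at -0.914 with those of sg-U6 1 and -0.738 with those of sg-MIAT 1. On the second component sg-MIAT 1 lay at -31.3 and sg-U6 1 at 37.6. A difference in library depth is argued against. With all libraries thinned to 13128977 counts, the correlation between the deviations of sg-MIAT 1 and sg-U6 1 averaged 0.731 over 20 draws. That depth is the total of sg-MIAT 1, which itself lost no counts. The total of sg-U6 1, 14877702, lay between those of sg-U6 2 (13579979) and sg-MIAT 2 (18257865). A few genes taking most of the counts is argued against too: the 100 most abundant genes took 33.5% of the counts of sg-MIAT 1 and 29.3% of those of sg-U6 1, a gap of 4.21 percentage points that puts these samples outside the range of the other 4, 30.5% to 31.6%, on opposite sides. A culture, day or library batch shared by samples with the same number may be involved but stays open: matching samples by number ranked 2 of 6 possible matchings by mean correlation (0.397, against 0.566 when numbers 2 and 3 are crossed), and the labels give no batch. The samples numbered 1 also had the fewest genes with at least 1 count, 15101 in sg-MIAT 1 and 15528 in sg-U6 1, against 15650 to 15794 in the other 4. In sg-U6 1 this was so despite a larger total (14877702) than in sg-U6 2 (13579979). Whether library complexity or RNA quality is involved was not tested. The pair holds 1 sample of each guide, and no biological explanation was tested.

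The larger count for sg-MIAT 1, sg-MIAT 2 and sg-U6 1 against the rest raised the possibility that sg-MIAT 3 and sg-U6 1 carry each other's labels. The groups as labelled held 9 genes with a gap of at least 2-fold between the lowest CPM of one group and the highest of the other (after adding 0.5 CPM to the latter), whereas the 8 splits that are neither the labels nor that swap held at most 2. The swapped split itself held 74 such genes. A swap would give the swapped split more such genes than the labelled one, which was seen. It would also leave the labelled split with no more than those 8, since every split is a single exchange from the swapped one, and this was not seen. These 2 results point in opposite directions, and the splits also differ in how they divide the same-numbered samples. The swapped split was also the only one with any edgeR calls, 4. It had 2420 genes at an unadjusted edgeR p under 0.05, against 477 as labelled. The split of sg-MIAT 1, sg-MIAT 3 and sg-U6 1 against the rest had more such genes, 2797, with 0 calls. With Miat not analysed here, a swap cannot be told apart from another structure of the samples.

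A hypothesis for follow-up is that the guide changes a small set of genes that the sample structure largely hides, prompted by the 9 genes that DESeq2 called in the full fit and with each sample left out. Of these, 7 are among the 9 with a gap of at least 2-fold, but both lists select genes that separate the same 6 samples, so their overlap is no evidence for the hypothesis. Under the block, 1 of the 4 splits that part all same-numbered pairs, the real one, gave as many DESeq2 calls as the real split (130, against a highest other of 52). With 4 such splits no share under 0.05 can be reached, so the hypothesis stays open.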
